A study of Streptococcus mutans UA159 with 24 samples.

How the data were processed

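The 24 arrays were custom Agilent two-colour arrays with oligonucleotide probes for Streptococcus mutans UA159, and each carried RNA of carolacton-treated biofilm in one dye and RNA of untreated biofilm of the same time in the other. Per the labels' protocols, biofilms were started at an optical density of 0.05 in wells of plates, total RNA was purified on columns, and the dyes were coupled to the RNA chemically. The deposited scanner files hold, per the file headers, spot intensity and local background intensity of both channels from Feature Extraction 10.5.1.1 with no normalization, beside processed signals that the software had background-subtracted and dye-normalized, and quality flags of each spot. The authors' series table holds log2 ratios of treated over untreated RNA, as their comparison with the scanner ratios showed (r = 0.918 to 0.997 over the spots of each array, column means of 0, medians from -0.0212 to 0.0541). How the authors normalized those ratios within arrays is not given in the sources used here. The submitters' processing notes name limma with its version not stated.

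Each array had 15744 spots, of which 15208 were not controls and 13791 belonged to 1952 open reading frames, with a median of 3 probes per gene and 2 spots per probe. The files give locus tags for 1945 of the genes and symbols for 725, and 1833 matched the reference gene table of assembly ASM746v2, which was used for names only. Coordinates are those of the array files, on the UA159 chromosome sequence that the files name. For 6 genes (2 with the symbol mubY and 4 without a symbol) 9 probe sequences are shared with another gene, and none of them is named in the results.

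From the scanner files, background was corrected by normexp with an offset of 50, and each array was normalized by loess with control spots at weight 0, in limma 3.58.1 under R 4.3.3. Controls were then removed, and spots flagged as outliers, a median of 2.3% per array, were left out. Ratios of dye-swapped arrays were turned so that all were treated over untreated. Spots of a probe were averaged, the median over the probes was taken as the gene's value, and the dye-swap arrays of a replicate were averaged. The probes of a gene had median SDs of 0.0163 to 0.0481 at the 5 times, and of the named genes atpH and gtfB at 20 min, cidA at 60 min and gtfB at 300 min had probes of both signs. Red signals had medians of 10400 to 19300 per array and green signals 3830 to 12000, over background medians of 38.0 to 67.5. The number of separate samples, not of arrays, limits the precision.

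Before averaging, labelled replicates were compared. The noise expected between the means of dye-swap pairs was taken from the differences between dye-swap arrays after removing each gene's common dye bias. Replicates that differed by less than this noise were counted as 1 sample, which turned the 12 labelled replicates into 8 samples. This departs from the design fixed before the data were examined, in which all 12 counted separately, and the fit as first fixed is given as an alternative. At 120 min both replicates were within the noise and no other pair of that time was there to compare. The labels call the replicates biological but do not say which cultures they came from, so p-values of single genes measure the spread between these samples.

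All 8 samples entered 1 limma fit with a mean per time and moderated variances (3 residual degrees of freedom, a median of 5.79 with the moderation). Ratios at 20, 60, 120 and 300 min were tested against 0, and neighbouring ones of these times against each other. The tests had Benjamini-Hochberg adjustment and a threshold of 0.05. At 40 min no test was made, because the design fixed for this time gave values only. The contrast of 300 with 20 min was added after the data were seen. Gene lists, 20 in all and fixed before the data were examined, were tested with camera at a preset correlation of 0.01, adjusted over the lists of a time. An estimated correlation and fry were alternatives. The preset treats the genes of a list as nearly independent. With it camera sets a list's genes against the other genes, so its p-values rest on the spread across genes, not across samples. The estimates ran from -0.0278 for the glucan and adhesin list to 0.518 for the pyrimidine list, with 0.361 for the F-ATPase list. For lists whose genes vary together, the adjusted p from the preset can therefore be far too small. The test with an estimated correlation has little power, because it also rests on the 3 residual degrees of freedom. For the glucan list at 60 min, whose estimate lies below the preset, the unadjusted camera p was 0.00889 with the preset and 0.0688 with the estimate. A list that fails with an estimated correlation is therefore not shown to be unshifted.

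The rule for named genes, also fixed beforehand, took per tested time the 8 highest and 8 lowest genes past the threshold with the same sign on every array, up to 4 members of each described list by size, and 5 per direction for each difference between times and at 40 min. It added 18 genes chosen in advance, of which 12 were found by symbol. The others were not looked up by locus tag, so they may be on the array. Ratios of some that were found, such as lrgA and cidA, are not given below. Because no gene passed at 20, 60 and 120 min with 8 samples, this rule used the threshold of the fit to the 12 labelled replicates. It named 217 genes. A gene not well above background in one condition on all arrays of a time was given as a bound. Levels of a single channel were taken after loess and quantile scaling of the arrays' mean log2 signals.

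The procedure was tested on simulated data with 200 of 1952 genes changed. For a log2 ratio of 1 it recovered 94% of genes at 20 min, 93% at 60 min, 47% at 120 min and 84% at 300 min, and for a log2 ratio of 2 it recovered 100%, 100%, 99% and 100%. Among 1752 unchanged genes it called 0, 0, 3 and 107. With the own spread of a time it called 4, 13 and 11 unchanged genes at 20, 60 and 300 min, and at 300 min it recovered 52% of genes with a log2 ratio of 1 and 100% of those with 2. In a simulation of 20 lists, camera found the 1 raised list and called 0 of the others. In these simulations all genes of a time had the same spread, varied independently, and the same genes were changed at each time. In the data at 20 min, 2 genes were higher and 6 lower at least 2-fold in every sample, and none passed. The shares recovered above therefore do not carry over to 20 and 60 min, and 0 calls there do not exclude 2-fold changes.

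Alternatives varied the background correction, the normalization within and between arrays, the handling of probes, dim genes and outlier spots, the dye swaps, the samples in the fit, the counting of replicates, blocks for replicate number and slide, the variance model and the authors' values. Each replicate was also left out in turn. Slides were known for all arrays, and each of the 3 slides held several times.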

Results

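Biofilms of Streptococcus mutans UA159, a bacterium of dental plaque, were grown for 3.5 h and then given fresh medium with or without 0.25 µg/ml carolacton, a natural product of a myxobacterium that disturbs biofilms of this species. RNA was taken after 20, 40, 60, 120 and 300 min. Each of 24 two-colour arrays set RNA of treated biofilm against RNA of untreated biofilm of the same time, and each labelled replicate was hybridised on 2 arrays with the dyes exchanged. The question was which genes respond to carolacton at each time and how the response differs between times. Every value below is a log2 ratio of treated over untreated biofilm for 1 of 1952 genes, so 0 is the untreated biofilm and 1 is a 2-fold higher level.

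The labels give 3 replicates at 20, 60 and 300 min, 2 at 120 min and 1 at 40 min. Replicates 2 and 3 at 20 min differed across genes by an SD of 0.0603, which was less than the 0.0721 expected from the noise between dye-swap arrays. The same held for replicates 2 and 3 at 60 min (0.0404 against 0.0601), for replicates 1 and 2 at 120 min (0.0382 against 0.0630) and for replicates 1 and 3 at 300 min (0.0495 against 0.137). The other pairs differed by 0.209 to 0.665. Each pair within the noise was counted as 1 sample, which left n = 2 at 20, 60 and 300 min and n = 1 at 40 and 120 min. Median signals per array were 10400 to 19300 in red and 3830 to 12000 in green over backgrounds of 38.0 to 67.5, and 93.95% to 96.98% of genes were well above background in both channels. Genes with a saturated channel numbered 0 to 7 per array on slide 1, 110 to 162 on slide 2 and 31 to 161 on slide 3. Whether saturation shaped the ratios of bright genes or the differences between slides was not tested. The number of samples, not of arrays, limits the precision.

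**Figure D1:**
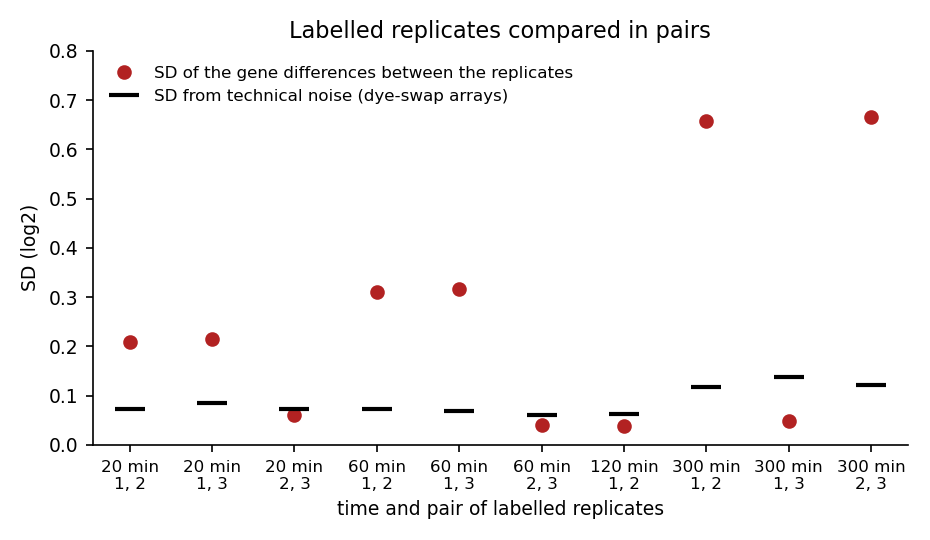
Each point is the SD over genes of the difference between a pair of labelled replicates (y axis, log2), and each bar is the SD that the noise between dye-swap arrays gives for that pair. The pairs 2, 3 at 20 min, 2, 3 at 60 min, 1, 2 at 120 min and 1, 3 at 300 min lie below their bar, and the other pairs lie at 0.209 or above.

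At 20 min the genes of pyrimidine synthesis were lower in the treated biofilms, and genes of the citrate branch of central metabolism were among the highest. The 12 measured members of the pyrimidine list fell as a group, with a median log2 ratio of -0.99 (camera adjusted p = 7.02e-11, and adjusted p = 0.622 with an estimated correlation), and 11 of them were lower in both samples. The operon pyrR to carB (positions 803417 to 810716 of the chromosome) held the lowest members. The subunit genes of carbamoyl phosphate synthase, pyrA and carB, were at -1.25 ± 0.29 and -1.23 ± 0.31 (SD, n = 2). The other genes of the operon were close to them, with pyrB, the aspartate carbamoyltransferase, at -1.19 ± 0.23, the uracil permease gene SMU.857 at -1.17 ± 0.20 and the regulator gene pyrR at -1.17 ± 0.18. On the other side, idh, citZ and citB, the genes of isocitrate dehydrogenase, citrate synthase and aconitase, were at 1.43 ± 0.55, 1.40 ± 0.53 and 1.21 ± 0.48. The pyruvate formate-lyase gene pfl was at 1.35 ± 1.12, a spread that nearly equals its mean, and gtfD, which makes soluble glucan from sucrose, was at 1.16 ± 0.25.

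Several smaller group shifts were measured at 20 min, all with an adjusted p of 0.622 when the correlation was estimated. The chaperone and protease list fell (median -0.24, camera adjusted p = 0.00314), with 11 of 15 members lower in both samples and the heat-shock genes grpE, hrcA and dnaK at -0.52 ± 0.40, -0.42 ± 0.34 and -0.36 ± 0.16. Its median was -0.13 without the merged replicates 2 and 3 (adjusted p = 0.0291). The DNA replication and repair list fell (median -0.11, adjusted p = 0.0115), with 25 of 39 members lower in both samples, among them recO at -0.64 ± 0.16 and mutL at -0.47 ± 0.22, and its median was -0.17 without replicate 1 (adjusted p = 0.0451). The branched-chain amino acid list rose (median 0.23, adjusted p = 0.00314), with 12 of 15 members higher in both samples and the transporter genes livM and livF at 0.30 ± 0.06 and 0.27 ± 0.04. The metal transport list rose (median 0.29, adjusted p = 0.0396), led by sloC, sloB and sloA of the manganese and iron transporter at 0.69 ± 0.02, 0.65 ± 0.13 and 0.54 ± 0.12. It lost the call without replicate 1 (adjusted p = 0.122) and with the 12 labelled replicates counted separately (0.0867). The fatty acid synthesis list (median 0.19, adjusted p = 0.0396) and the list of sugar transport and use (median 0.18, adjusted p = 0.0356) also rose, with 9 of 11 and 33 of 50 members higher in both samples. The fatty acid list lost the call without either sample (adjusted p = 0.0813 without replicate 1 and 0.125 without the others), and the sugar list without replicates 2 and 3 (median 0.08, adjusted p = 0.255). In the sugar list the members with the largest ratios went the other way, bglA being at -0.79 ± 0.00446 and celA at -0.58 ± 0.33, both genes of beta-glucoside use. The pyruvate and fermentation list rose (median 0.11, mean 0.35, adjusted p = 0.0358), with 15 of 22 members higher in both samples, and the citrate genes above are 3 of its members. It too lost the call with the 12 replicates (adjusted p = 0.0812), and 6 of the 8 lists kept theirs. The other 12 lists did not pass, with adjusted p from 0.118 to 0.993. The median of each of the 8 lists that did had the same sign on all 3 slides, but slides 2 and 3 hold the merged replicates. With the slide as a fixed block and the third slide left out, 7 lists passed.

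No single gene passed at 20 min in limma's test over all genes (smallest adjusted p = 0.401), while 162 of 1952 genes had an unadjusted p under 0.05 (91 higher, 71 lower) against 97.6 expected by chance. That number was 62 without replicate 1 and 30 without replicates 2 and 3. Adjusted over the list alone, 9 of the 12 pyrimidine members were lower, and 3 metal transport, 2 pyruvate, 2 glucan and adhesin, 2 competence and bacteriocin and 1 autolysin member were higher. With the 12 labelled replicates counted separately, limma called 342 genes, and from the spread of the 20 min samples alone it called 148. Of the genes fixed in advance, comD and comE, the competence sensor and regulator, were at 0.04 ± 0.03 and 0.02 ± 0.04, pknB, the serine/threonine kinase, at 0.06 ± 0.03, and folD, of one-carbon metabolism, at 0.03 ± 0.02.

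At 40 min the labels give 1 replicate, so the values have no replicate check, and the design fixed beforehand set no test for this time. The pyrimidine genes were again among the lowest: SMU.857 was at -1.05, pyrA at -1.04, pyrR at -1.02 and pyrB at -1.01, and all 12 members of the list were below 0 (median -0.94). SMU.503c, a gene of unknown function, was the lowest at -1.10. The highest were 4 neighbouring genes, SMU.1068c at 1.01, SMU.1070c at 0.99, SMU.1069c at 0.98 and SMU.1067c at 0.95, which include the 2 parts of a putative ABC transporter, and SMU.941c at 0.97. The 15 members of the branched-chain amino acid list were all above 0 (median 0.12), and 32 of 39 members of the DNA replication and repair list were below 0 (median -0.08). Across genes, the 40 min ratios correlated with the 20 min means at r = 0.763 and with the 60 min means at r = 0.775; genes are not independent replicates.

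At 60 min several genes of glucan synthesis and surface proteins had higher mean ratios in the treated biofilms, and several of defence against peroxides had lower ones. None of them passed over all genes, and no member of the oxidative stress list passed when adjusted over that list alone. The list of glucan and fructan synthesis and surface adhesins rose (median 0.23, camera adjusted p = 0.0296, and adjusted p = 0.688 with an estimated correlation), but lost the call without replicate 1 (adjusted p = 0.0501) and with the 12 labelled replicates counted separately (0.107). Its members gtfD and gtfB were at 1.62 ± 0.71 and 1.01 ± 0.17 (n = 2), and gtfB makes insoluble glucan. The cell wall protein gene wapE was at 1.54 ± 0.55 and the glucan-binding protein gene gbpD at 0.96 ± 0.40. Of its 14 members 10 were higher and 4 lower in both samples, and the adhesin gene spaP, picked after its value was seen, was at -0.70 ± 0.16. Adjusted over the list alone, 5 of its members were higher and 1 lower, and of the other lists 3 metal transport, 2 competence and bacteriocin and 1 autolysin member were higher. The oxidative stress list fell (median -0.32, adjusted p = 0.00363, and 0.732 as the adjusted p with an estimated correlation), with 9 of 13 members lower in both samples. Without replicate 1 its median was -0.20 and the call was lost (adjusted p = 0.331), and without replicates 2 and 3 the median was -0.55. The alkyl hydroperoxide reductase genes ahpC and ahpF were at -0.63 ± 0.48 and -0.58 ± 0.46, the superoxide dismutase gene sod at -0.57 ± 0.52 and the thiol peroxidase gene tpx at -0.76 ± 1.09.

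The pyrimidine list did not pass at 60 min (median -0.15, adjusted p = 0.214), and its samples disagreed in sign. The values of pyrB and pyrR were -0.18 ± 0.69 and -0.12 ± 0.61. The list median was -0.551 in replicate 1 and 0.223 and 0.206 in replicates 2 and 3. For the other 4 lists that passed, the adjusted p was 0.688 to 0.732 with an estimated correlation. The DNA replication and repair list fell (median -0.12, adjusted p = 0.00363), with 29 of 39 members lower in both samples. The competence and bacteriocin list fell too (median -0.15, adjusted p = 0.00999), with 31 of 46 lower in both samples, and lost the call without replicate 1 (median -0.10, adjusted p = 0.291) and with the 12 labelled replicates counted separately (0.0813). Its median was -0.23 without replicates 2 and 3. The bacteriocin region genes SMU.152 and SMU.151 were at -0.82 ± 0.23 and -0.72 ± 0.00407, while SMU.1896c and SMU.1895c of the same list were higher at 1.43 ± 0.20 and 1.40 ± 0.14. The sugar list (median 0.11, adjusted p = 0.00846) and the branched-chain amino acid list (median 0.14, adjusted p = 0.0208) rose, with 34 of 50 and 13 of 15 members higher in both samples. The sugar list lost the call without replicate 1 (adjusted p = 0.102), with a median of 0.17 without replicates 2 and 3. The branched-chain list lost it without replicates 2 and 3 (adjusted p = 0.195), with a median of 0.27 without replicate 1. For the 6 lists that passed the sign of the median was the same on all 3 slides, but slides 2 and 3 hold the merged replicates. The other 14 lists did not pass (adjusted p from 0.0622 to 0.653).

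Among single genes at 60 min, SMU.503c was the lowest at -2.10 ± 1.15, and the ribonucleotide reductase genes nrdF and nrdE were at -0.99 ± 0.17 and -0.94 ± 0.15. The ammonium transporter gene nrgA and its neighbour SMU.1657c, a nitrogen regulatory protein gene, were at 1.21 ± 0.86 and 1.08 ± 0.82. The sensor kinase gene covS (SMU.1516, the VicK-like kinase) was at 0.62 ± 0.44, comD at -0.50 ± 0.42 and comE at -0.49 ± 0.48. limma called none of the 1952 genes (smallest adjusted p = 0.216), and 252 had an unadjusted p under 0.05 (166 higher, 86 lower), with 175 without replicate 1 and 64 without replicates 2 and 3. With the 12 labelled replicates counted separately it called 519, and without replicate 1 only the branched-chain and the DNA replication and repair list passed, against 8 without the merged replicates 2 and 3. With the slide as a fixed block and the third slide left out, 7 lists passed.

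At 120 min a gene cluster for a nonribosomal peptide and polyketide product held many of the highest genes in the treated biofilm, and a bacteriocin region many of the lowest. In the 1 sample, bacA1 was at 2.26, mubB at 2.16, mubH at 2.02, mubG at 1.98, bacD at 1.92, mubZ at 1.90 and mubM at 1.88. They lie in one chromosome region with synthetases, a polyketide synthase, a transporter and a hydrolase. SMU.153, SMU.152, SMU.151 and SMU.150, 4 neighbouring genes that include those of a bacteriocin, were at -2.46, -2.40, -2.24 and -2.16. SMU.503c was the lowest at -2.65. SMU.11 was not well above background in treated biofilm on all 4 arrays, so its level in that sample was at least 1.53-fold lower. That bound sets the untreated mean against the lowest signal well above background.

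With 1 sample the list values of 120 min have no replicate check of their own. The pyrimidine list, which had fallen at 20 min, had a median of 0.65 at 120 min, with 11 of 12 members above 0, carB at 0.78, pyrB at 0.70 and pyrR at 0.52. The folate and one-carbon list had a median of 0.28, with 12 of 14 members above 0 and serB, a serine synthesis gene, at 1.68. The branched-chain amino acid list had a median of 0.37 with 14 of 15 members above 0, and leuD and leuC were at 0.82. The two-component list had a median of 0.26 with 23 of 29 members above 0, among them SMU.659 at 0.89 and covS at 0.69. The purine list had a median of -0.30 with 13 of 14 members below 0 and purL at -0.70. The cysteine and methionine list had a median of -0.18 with 10 of 11 below 0, metC at -1.35 and metB at -1.27. The DNA replication and repair list had a median of -0.25 with 30 of 39 below 0 and recO at -1.43 and recF at -1.09, although gyrA was at 0.94. The competence and bacteriocin list had a median of -0.16 with 30 of 46 below 0. The glucan and adhesin list had a median of 0.59 with 8 of 14 members above 0, gtfD, gbpC and gtfB at 1.73, 1.62 and 1.34, and, picked after their values were seen, gbpA at -0.33 and spaP at -0.20.

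The tests of 120 min borrow their spread from the other times and hold only if the 1 sample varies as those samples do. On that assumption SMU.11 had an adjusted p of 0.0617 in limma, and the 8 lists above, other than the glucan and adhesin list, had camera adjusted p of 0.0171 to 0.0319, and 0.750 with an estimated correlation. The other 12 had adjusted p from 0.103 to 0.923. Adjusted over the list alone, 4 glucan and adhesin, 3 competence and bacteriocin, 2 two-component, 1 folate, 1 cysteine and methionine and 1 autolysin member were higher. Lower were 6 competence and bacteriocin, 3 cysteine and methionine, 1 fatty acid, 1 pyruvate and 1 DNA replication and repair member. The medians of the 8 had the same sign on both slides that hold this time. That is no separate check, because the replicates on these slides were within the noise and counted as 1 sample. limma called none of the 1952 genes (smallest adjusted p = 0.0617, with 118 genes under 0.1), while 399 had an unadjusted p under 0.05 (251 higher, 148 lower). It called 565 genes with the 2 labelled replicates of 120 min counted as 2 samples, 811 with all 12 counted separately and 505 with the 300 min samples left out.

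At 300 min the 8 highest of all genes were pyrimidine genes, and 11 of the 12 members of the list rose. The ratio of pyrK, a subunit of dihydroorotate dehydrogenase, was 3.37 ± 0.07 (10.4-fold, n = 2, adjusted p = 0.00126 in limma). Next came pyrDB at 3.21 ± 0.06, SMU.857 at 2.99 ± 0.48, pyrR at 2.94 ± 0.71, pyrF at 2.65 ± 0.12, pyrB at 2.65 ± 0.52, pyrA at 2.54 ± 0.38 and carB at 2.45 ± 0.33. The list median was 2.59 (camera adjusted p = 9.44e-05, and adjusted p = 0.775 with an estimated correlation), and it was 2.29 to 2.76 on the 3 slides. The one member that fell was pyrG, the CTP synthase gene, at -1.04 ± 0.10; it lies outside the rule for named genes and was picked after its value was seen. Among the lowest genes were gidA, a tRNA modification gene, at -2.83 ± 1.29, the cobalt transporter genes SMU.2148c at -2.26 ± 0.16 and cbiO (SMU.2149c) at -2.10 ± 0.29, and dnaC, the replicative helicase gene, at -2.04 ± 0.56. Of the competence and bacteriocin list, SMU.1913c was at -2.24 ± 0.45, SMU.1904c at -2.22 ± 0.45, SMU.1908c at -2.17 ± 0.42 and SMU.1912c at -2.16 ± 0.33.

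**Figure D2:**
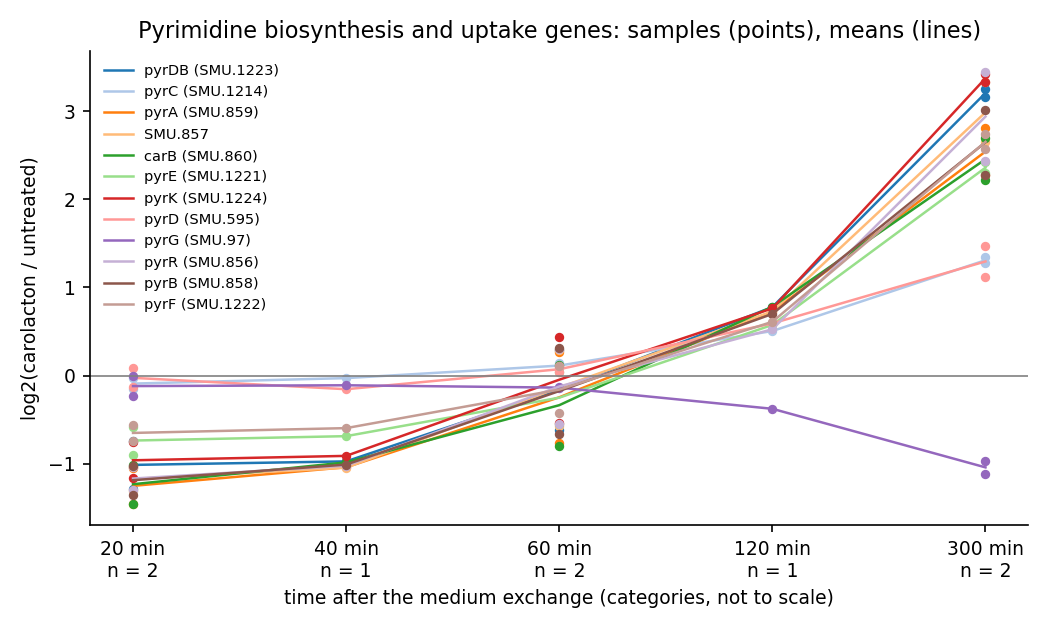
The y axis gives the log2 ratio of treated over untreated biofilm for the 12 pyrimidine genes, the x axis the 5 times as categories, points the samples and lines the means. At 20 min 11 of the 12 genes lie below 0 in both samples, and at 300 min 11 rose and pyrG fell, with pyrK highest at 3.37.

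**Figure D3:**
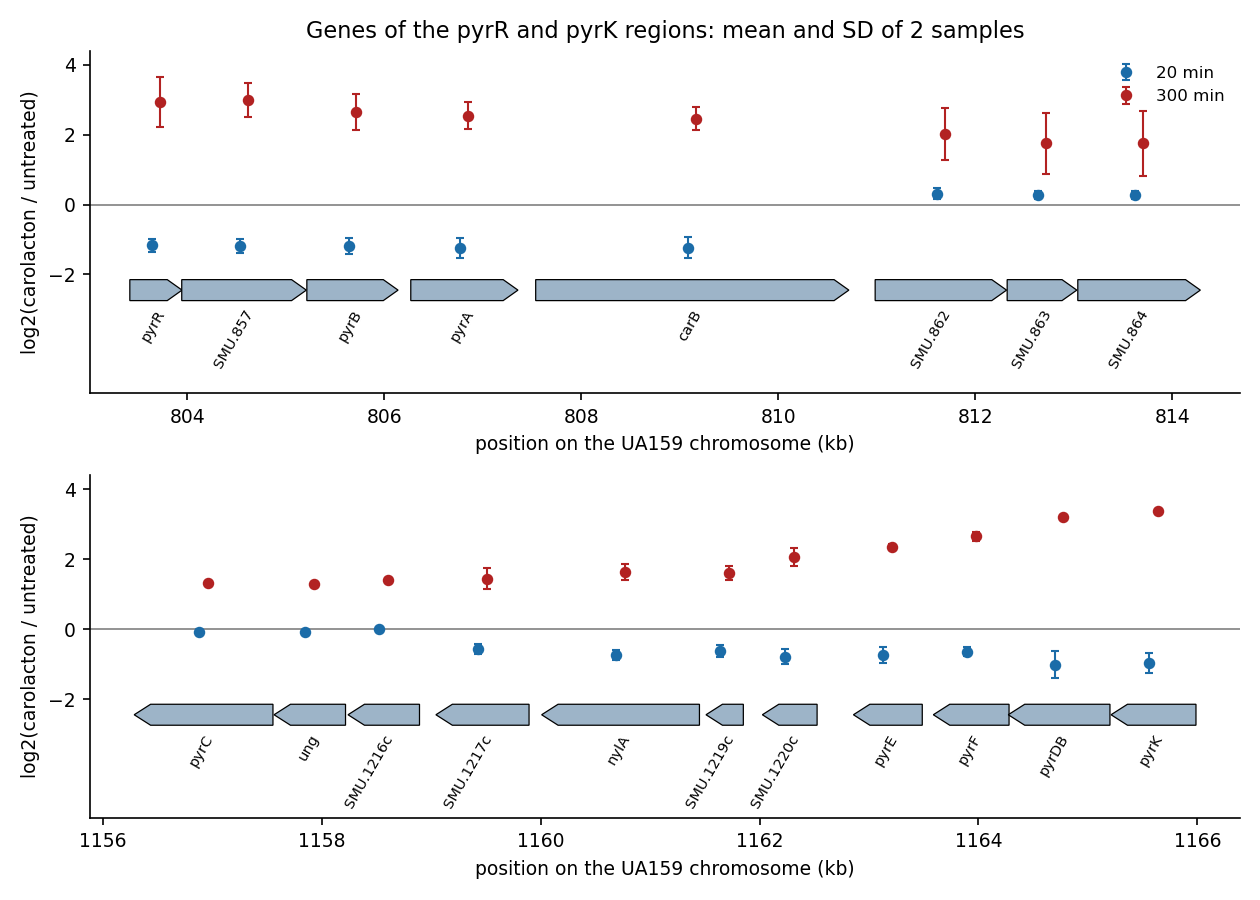
Arrows show the genes of the regions 803417 to 814284 (upper panel) and 1156286 to 1165988 (lower panel) to scale on the chromosome (x axis, kb) and point along the coding strand, and points give each gene's mean log2 ratio with its SD (y axis, n = 2). In the upper panel the ratios at 20 min are between -1.25 and -1.17 from pyrR to carB, and at 300 min all genes of both panels are above 1.

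Regulators, the proton ATPase, ribosomal proteins and DNA repair genes also shifted at 300 min. For each of these lists, and for the competence list, the adjusted p was 0.775 with an estimated correlation. The two-component list rose (median 0.53, adjusted p = 0.0019), with 16 of 29 members higher and 2 lower. The response regulator gene SMU.1038c and its kinase gene SMU.1037c were at 1.80 ± 0.28 and 1.65 ± 0.33, SMU.659 at 1.45 ± 0.03, SMU.927 at 1.37 ± 0.18 and covS at 1.08 ± 0.21. The list of the F-ATPase, malolactic and agmatine systems fell (median -0.65, adjusted p = 0.0135), with 8 of 13 members lower and none higher, and its median was -1.07 without replicate 2. The ATPase genes atpC (SMU.1529), atpB and atpC (SMU.1527) were at -1.13 ± 0.14, -1.10 ± 0.12 and -1.04 ± 0.14. The DNA replication and repair list fell (median -0.34, adjusted p = 0.0135), with 19 of 39 members lower and 5 higher. The mismatch repair genes mutS and mutL were at -1.65 ± 0.70 and -1.55 ± 0.55, while gyrA, a gyrase subunit gene, rose to 1.98 ± 0.19.

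The ribosomal protein list fell (median -0.23, adjusted p = 0.0135), with 16 of 48 members lower and 4 higher, rplI at -1.65 ± 0.62 and rpsQ at -1.31 ± 0.49. Its median was -0.474, -0.00366 and -0.497 on the 3 slides, and the adjusted p was 0.114 without the merged replicates 1 and 3. The competence and bacteriocin list fell (median -0.55, adjusted p = 0.0189), with 24 of 46 members lower and 6 higher. It lost the call without replicate 2 (adjusted p = 0.206) and with the 12 replicates counted separately (0.0663). For the 6 lists that passed, fry, which asks only whether a list's members move one way on balance, gave adjusted p of 0.0143 to 0.0312. It does not single them out, because it also passed lists that camera did not. It gave 0.0234 for the folate, autolysin, peptidoglycan and glucan lists and 0.04585 for the fatty acid list. At 20 and 60 min the smallest adjusted p from fry were 0.383 and 0.192, so it passed no list there.

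**Figure D4:**
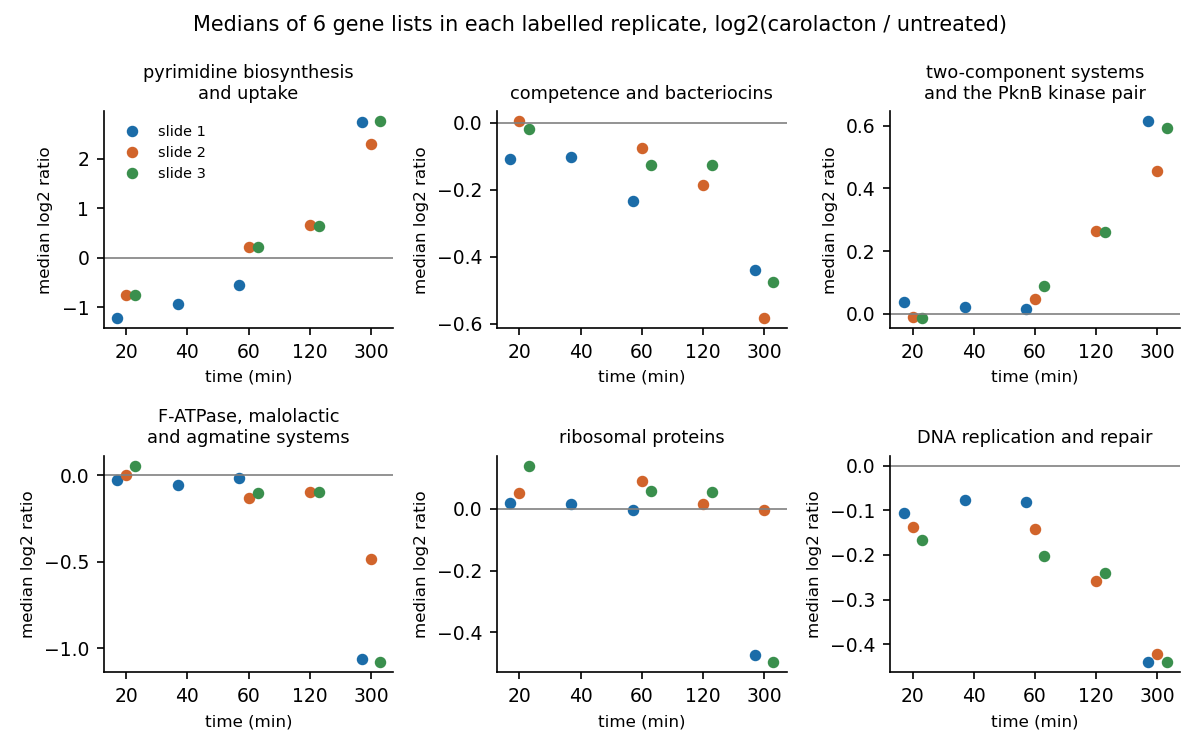
Each panel shows for 1 gene list the median log2 ratio of its members (y axis) in each labelled replicate, coloured by slide, at the 5 times (x axis, min, as categories). The 6 lists are those that passed at 300 min, and in the ribosomal panel the slide 2 replicate at 300 min lies at -0.00366 against -0.474 and -0.497 for the others.

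Genes of the cell envelope went both ways at 300 min. In the peptidoglycan and cell division list 8 of 36 members were higher and 10 lower (adjusted p of the list 0.488). The cell shape genes mreC and mreD fell to -2.24 ± 0.45 and -2.03 ± 0.27, murG, of the lipid II pathway, to -1.62 ± 0.18, and pbp2a to -1.43 ± 0.13. In the glucan and adhesin list 5 of 14 were higher and 2 lower (0.554), with the glucan-binding protein gene gbpC at 1.95 ± 0.35, wapA at 1.56 ± 0.89 and the sortase gene srtA at 1.34 ± 0.12. gtfD (0.26 ± 0.35), gtfC (0.50 ± 0.82) and gtfB (0.13 ± 1.59, from -0.9955 in one sample to 1.256 in the other, with probes of both signs) did not pass. Of 10 autolysin and holin-like members 5 were higher and none lower (0.169), and of 11 fatty acid synthesis members 1 was higher and 3 lower (0.114).

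In metabolism at 300 min, 6 of 14 folate and one-carbon members were higher and none lower (adjusted p of the list 0.0677), with serB at 1.93 ± 0.58 and folC at 1.08 ± 0.13. The value of folD, 0.16 ± 0.54, did not pass. Of 11 cysteine and methionine members 1 was higher and 4 lower (0.263), with cysE at -1.48 ± 0.80 and metC at -1.17 ± 0.05. Of 15 branched-chain amino acid members 5 were higher and 4 lower (0.554). The synthesis genes ilvB and ilvH were at 1.27 ± 0.20 and 1.16 ± 0.23, and the transporter gene livF was at -1.15 ± 0.26. The purine list had 3 of 14 higher and 4 lower (0.488), sugar transport and use 11 of 50 higher and 7 lower (0.714), and pyruvate metabolism 3 of 22 higher and 2 lower (0.980), with pflC at -1.21 ± 0.00799. Of 12 metal transport members 1 was higher and 3 lower (0.587), with the zinc transporter genes adcB and adcC at -1.26 ± 0.35 and -1.14 ± 0.47. Of 19 aminoacyl-tRNA synthetases 4 were higher and 5 lower (0.624), with thrS and lysS at 1.22 ± 0.23 and 1.13 ± 0.10 and cysS at -1.58 ± 0.68. Of 15 chaperones and proteases none was higher and 2 were lower (0.624). Of 13 oxidative stress members 5 were higher and 1 lower (0.695), and tpx and ahpC, at 1.64 ± 0.26 and 1.34 ± 0.76, lost the call without the merged replicates 1 and 3. In the sugar, pyruvate, metal transport and chaperone lists, which did not pass, the median was above 0 and the direction of the test downward. Median, mean and test also differed in sign at 20 min in the two-component, autolysin, F-ATPase and synthetase lists and at 120 min in the peptidoglycan, fatty acid, chaperone, oxidative stress and sugar lists, none of which passed then.

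In all, limma called 878 of 1952 genes at 300 min, 486 higher and 392 lower, of which 338 changed at least 2-fold. Adjusted over the list alone the counts given for the lists moved in 8 of them: 17 two-component, 7 competence, 9 peptidoglycan, 8 sugar, 5 synthetase and 6 DNA repair members were then higher, 9 F-ATPase members lower and 0 chaperones lower. From the spread of the 300 min samples alone it called 258 (144 higher, 114 lower), 257 of them shared with the 878. In simulated data the shared spread gave 107 false calls among 1752 unchanged genes at 300 min against 11 from the own spread. All single genes given above for 300 min as values past the threshold also passed with the own spread, except pyrG, for which this was not run. The genes fixed in advance comD (-0.81 ± 0.40), comE (-0.72 ± 0.27) and pknB (0.50 ± 0.24) passed with the shared spread and not with the own spread. The count was 1324 without replicate 2, 1423 with the 12 replicates counted separately, 877 with the slide as a random block and 785 with it as a fixed block without the third slide.

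Set against each other, the responses at 20 and 300 min went opposite ways for most of the pyrimidine genes, while pyrG was lower at 300 min. The difference of 300 minus 20 min, a contrast added after the data were seen, was 4.34 (SE 0.34, adjusted p = 0.00662) for pyrK, 4.22 (SE 0.34) for pyrDB, 4.16 (SE 0.36) for SMU.857, 4.11 (SE 0.42) for pyrR and 3.83 (SE 0.40) for pyrB. In the other direction it was -2.83 (SE 0.46, adjusted p = 0.0122) for SMU.936 and -2.78 (SE 0.62, adjusted p = 0.0268) for SMU.935, both of an amino acid transporter. It was -2.78 (SE 0.24, adjusted p = 0.00662) for mreC, which was at 0.54 at 20 min and -2.24 at 300 min, and -2.44 (SE 0.60, adjusted p = 0.0337) for gidA. limma called 517 genes in this contrast, 298 higher and 219 lower. It called 0 genes without either sample of 20 min (492 and 455 at an unadjusted p under 0.05). The count was 1127 without replicate 2 of 300 min, 931 without its merged replicates 1 and 3, 243 from these 2 times alone and 1199 with the 12 replicates counted separately. It called 467 with the slide as a random block and 349 with it as a fixed block without the third slide.

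The planned differences between neighbouring times called no gene with limma. At an unadjusted p under 0.05, 97.6 of the 1952 genes are expected by chance in each difference. For 60 minus 20 min there were 36, fewer than that. gbpC was at 0.94 (SE 0.27) and nrdF and nrdE at -1.24 (SE 0.28) and -1.14 (SE 0.25), all far from the threshold after adjustment. For 120 minus 60 min there were 89, with bacA1 at 2.01 (SE 0.48), mubB at 1.96 (SE 0.41) and mubH at 1.87 (SE 0.34), all with an adjusted p of 0.542. For 300 minus 120 min there were 427, with pyrK at 2.61 (SE 0.42), pyrDB at 2.43 (SE 0.42) and SMU.941c at -2.66 (SE 0.45), all with an adjusted p of 0.0829. The count for 300 minus 120 min was 758 without replicate 2 of 300 min and 507 without its merged replicates 1 and 3. At an unadjusted p under 0.05 there were 14 to 54 genes for 60 minus 20 min and 38 to 109 for 120 minus 60 min when 1 replicate or merged sample was left out. With the 12 labelled replicates counted separately the counts of called genes were 11, 137 and 844.

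Over all genes, the spread of the ratios was wider at the late times than at the early ones. The SD of the gene means was 0.269 at 20 min, 0.205 at 40 min, 0.299 at 60 min, 0.531 at 120 min and 0.757 at 300 min. Ratios of at least 2-fold in every sample were found for 2 genes higher and 6 lower at 20 min, 1 and 5 at 40 min, 4 and 1 at 60 min, 90 and 49 at 120 min and 118 and 75 at 300 min. With 1 sample at 40 and 120 min this condition is easier to meet there. Across genes, the 2 samples of a time correlated at r = 0.764 at 20 min, 0.609 at 60 min and 0.693 at 300 min. The ratios of neighbouring tested times, as means or as the 1 sample of 120 min, correlated at r = 0.590 for 20 and 60 min. The correlation was 0.754 for 60 and 120 min, 0.621 for 120 and 300 min, and 0.0424 for 20 and 300 min.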

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

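The tests weighed here, and the contrast of 300 with 20 min, were chosen after the results were seen; for the untreated levels the bounds were set before those levels were computed. Of 1952 genes, 517 differed between 300 and 20 min in limma's test of the difference. Of the lists, 6 differed with camera, and for each of them the adjusted p was 0.758 with an estimated correlation. The pyrimidine list differed by a median log2 ratio of 3.74 (camera adjusted p = 9.84e-07), with list medians of -1.23 and -0.75 in the samples of 20 min and 2.75 and 2.29 in those of 300 min. The fatty acid synthesis list differed by -0.5131 (adjusted p = 0.0329) and was above 0 in both samples of 20 min (0.15 and 0.19) and below 0 in both of 300 min (-0.12 and -0.49). The ribosomal protein list differed by -0.2384 (adjusted p = 0.00538), with medians of 0.02 and 0.09 at 20 min and -0.49 and -0.00366 at 300 min. The two-component list (0.47, adjusted p = 0.000276), the F-ATPase list (-0.71, adjusted p = 0.0329) and the competence list (-0.48, adjusted p = 0.0329) differed too.

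Some probes between genes, which no comparison of the report uses, carried a signal. The median green signal was 869 for intergenic spots, 775.5 for foreign-gene spots and 7950 for spots of genes. At 300 min 289 of 1177 intergenic targets passed limma's test, 112 higher and 177 lower, while 0 of 6 foreign-gene targets were well above background, with log2 ratios of 0.0338 to 0.194. Of the 1177, 441 (37.47%) were well above background on at least 50% of arrays, and so were 180 of the 289 that changed. Of the 288 changed targets with a gene on each side, 204 had at least 1 flanking gene that changed the same way, 26 only such a gene that changed the opposite way, and 58 none that changed. Among the changed targets well above background, 146 had such a gene that changed the same way. How many would have one by chance was not computed, and at 300 min 486 of all 1952 genes were higher and 392 lower. The targets between pyrB and pyrA (806141 to 806268), pyrA and carB (807358 to 807536) and carB and SMU.862 (810717 to 810982), picked after their values were seen, were at 2.64 ± 0.34, 2.54 ± 0.32 and 3.18 ± 0.78 (SD, n = 2, adjusted p = 0.00552 each in limma).

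As a group, the pyrimidine genes were lower at 20 min and higher at 300 min, except pyrG, which was lower at 300 min. The within-array normalization is argued against as the cause, because the list median was at most -0.8894 at 20 min and at least 2.33 at 300 min under every normalization run. Deviating probes and dye bias are argued against too, since 91.67% of the 36 probes of the members were below 0 at 20 min and above 0 at 300 min, and the higher of the medians in the dye orientations was -0.9202 at 20 min and the lower was 2.518 at 300 min. A response of pyrimidine genes to carolacton that turns with time may therefore be the source, which is a hypothesis from the same data. A course of the untreated biofilm's own genes stays open as a part of the change: between 20 and 300 min the list's median level moved by -1.366 to -0.7078 in the untreated channel and by 2.633 to 2.994 in the treated channel on the 3 slides, and the untreated part was 21.43% and 32.29% of the ratio's rise on the second and first slide, on either side of the bound set for excluding it.

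The samples at 60 min differed from each other in the sign of the pyrimidine genes. A slide effect common to all times is argued against, because the difference between the samples correlated across genes at -0.1985 with that at 300 min and at 0.192 with that at 20 min. A different progress along the time course cannot be told apart from other causes: the difference correlated with the change from 20 to 300 min at 0.281 on the first slide and 0.1129 on the second, between the bounds set for a decision. Replicates 2 and 3 were closer to the 120 min sample (r = 0.810) than replicate 1 was (0.490), but they share their slides with it while replicate 1 lies on another, and both were alike in their correlation with 40 min (0.710 and 0.681). No other biological explanation was tested.

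The ratios were spread wider at 300 than at 20 min. Dim genes are argued against as the cause, since in the brightest 651 genes the SD was 2.962 times as large at 300 min (0.762 against 0.257). A few genes with large ratios are argued against, since the median absolute deviation was 3.987 times as large (0.689 against 0.173). A response of more genes at the late time may be the source, as a hypothesis, and a difference in growth between treated and untreated biofilm stays open, as untested.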

How the results depend on the processing

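The alternatives on the counting of replicates, the left-out 300 min samples, the fixed slide block and all of those for 300 minus 20 min were added after the data were seen; the others were planned. Background correction, normalization, probe, spot and filter choices, the variance model and the authors' values gave 854 to 900 genes at 300 min against 878. They gave 0 genes wherever the count was 0, except 32 genes at 120 min from the arrays with treated RNA in Cy5. Quantile scaling between arrays left every ratio as it was by construction. No scaling moved the median of all genes by over 0.1.

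Counting replicates or arrays separately raised the counts. With dye swaps as separate arrays, 99 genes were called at 20 min, 168 at 60 min and 342 at 120 min, and 11, 39 and 329 in the differences of 60 and 20, 120 and 60, and 300 and 120 min. With the 12 labelled replicates counted separately the counts were 342, 519, 811 and 1423 at 20, 60, 120 and 300 min, 11, 137 and 844 in those differences and 1199 for 300 minus 20 min. With the sample as a random block among the 12, they were 23, 56 and 220 at 20, 60 and 120 min and 216 for 300 minus 120 min. Counting the replicates of 120 min as 2 samples gave 565 genes at 120 min, 454 for 300 minus 120 min and 785 for 300 minus 20 min, and leaving out the 300 min samples gave 505 at 120 min. From the compared times alone, limma called 148 genes at 20 min, 258 at 300 min and 243 for 300 minus 20 min; at 120 min this model could not be fitted with 1 sample. The main fit shares 1 spread over all times. Replicates 1 and 2 differed by an SD of 0.209 at 20 min, 0.311 at 60 min and 0.657 at 300 min. Without the 300 min samples, 468 genes at 20 min and 648 at 60 min had an unadjusted p under 0.05. With those samples there were 162 and 252, and none passed after adjustment either way. The spread at 300 min thus weakened the early tests, and other causes were not tested.

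Leaving out 1 replicate or merged sample gave 876 to 1324 genes at 300 min, 0 to 758 for 300 minus 120 min and 0 to 1127 for 300 minus 20 min, and 0 at the other times. Where this left 1 sample in a time, that sample was assumed to vary like the others. Lists past the threshold were 6 to 7 at 20 min, 2 to 8 at 60 min, 8 at 120 min and 6 at 300 min. With a correlation estimated by camera 0 lists passed at 20, 60, 120 and 300 min, and with fry in place of camera 0, 0, 0 and 11. The value of gtfB at 300 min turned to -0.9955 without replicate 2 and was 1.256 without the merged replicates 1 and 3.

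The replicate numbers did not pair the samples at all times. The deviations of equal numbers correlated at 0.192 between 20 and 60 min, over the threshold of 0.1. The correlation was -0.166 between 20 and 300 min and -0.199 between 60 and 300 min. With the replicate block the counts were 784 at 300 min, 357 for 300 minus 20 min and 0 elsewhere (0 in limma without the block). Among the named genes at 300 min, 58 values over all alternatives lost the threshold, 29 of them from the spread of 300 min alone, and 25 gained it. At 20, 60 and 120 min 118, 114 and 299 gained it and 0 lost it. At 40 min the SD over genes was 0.190 to 0.263 against 0.205, and 3 single values moved. Signal over background limits SMU.11 and lrgA at 120 min. With at most 2 samples in a time, no other splits of the samples were counted.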

Other observations

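The groups of neighbouring genes given here were picked by size after the data were seen. The run of 14 genes from SMU.1260c to hisC (positions 1192355 to 1202643), which holds the histidine synthesis genes and serB, was at a mean log2 ratio of 1.89 at 300 min. No test of the run as a set was made. Among its genes were hisA at 2.01 ± 0.33, hisH at 2.07 ± 0.38 and hisG, of the first step, at 1.53 ± 0.68 (SD, n = 2, adjusted p of 0.00126, 0.00126 and 0.00438 in limma). The mean was 1.63 in the 1 sample of 120 min. At that time the run of 9 genes from SMU.530c to trpA (496725 to 504725), with the tryptophan synthesis genes, was at a mean of 1.21. The run of 6 genes from SMU.1037c to SMU.1042 (985855 to 991673), which holds the kinase and regulator genes of the report and the ABC transporter gene SMU.1041, was at a mean of 1.91 at 300 min. Among them were SMU.1041 at 2.16 ± 0.37 and SMU.1042 at 2.36 ± 0.51 (adjusted p of 0.00126 and 0.0013 in limma).

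The cluster from sfp to bacT (1255084 to 1288292) was at a mean of 1.83 over 13 genes at 120 min, and its first 9 genes, sfp to bacA1, were at 1.42 at 300 min. Among these were bacD at 1.55 ± 0.21 and mubB at 1.55 ± 0.22 (adjusted p of 0.00317 and 0.00439 in limma). Genes of glutamine and glutamate synthesis, glnR, glnA, gltA, gltD and SMU.367, were at a mean of 0.87 at 20 min, and glnQ to glnP, a transporter, at 1.02; none passed limma's test at that time. The amino acid transporter genes SMU.933 to SMU.936 were at a mean of 1.38 at 20 min, and SMU.932 to SMU.936 at -0.73 at 60 min. The runs were found past a log2 ratio of 0.5 at 20 to 60 min and of 1 at 120 and 300 min, so their lengths do not compare between those times. Lower runs of at least 4 genes were found at 120 and 300 min too, such as pth to tilS at a mean of -1.50 at 120 min. All lower runs of these 2 times lay at 4663 to 155469 or 1787987 to 2012800. All higher ones lay between 496725 and 1369907. Whether chromosome position bears on the list shifts was not tested. In shuffled gene order, the longest stretch past these limits had 3 to 5 genes. Shuffling breaks up operons, so longer runs in the real order say nothing about carolacton.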
